A study of Homo sapiens with 8 samples.

How the data were processed

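Total RNA was measured by sequencing in U2OS cells, a human osteosarcoma line, transfected with a mismatch control siRNA or with an siRNA against ZNF598 and then left unstimulated or given 2 ng/ml IL-1 beta for 1 h. Each of the 4 groups had 2 libraries, 8 in all, which the series calls biological duplicates. RNA was depleted of ribosomal RNA and libraries were made with the NEBNext Ultra II Directional kit, per the labels. Reads were trimmed with Trim Galore 0.4.2 and aligned to hg19 with STAR 2.5.2b-0, per the submitters' processing notes. Differential expression came from DESeq2, run by the authors, whose version is not given in the sources used here. The counting tool and the unit it counted in are not given in the sources used here either.

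The 4 tables used here hold comparison results only: the IL-1 effect in control siRNA cells, the IL-1 effect in ZNF598 siRNA cells, the siRNA effect in unstimulated cells and the siRNA effect in IL-1 cells. Each lists the same 15789 transcripts, of which 273 had no symbol; 1 symbol was listed for more than 1 transcript. The deposited mean over the 8 libraries is a normalized signal on a coverage-like scale, far above read counts. The deposited effect is a log2 fold change with a standard error. The deposited score is the Wald statistic, the log2 fold change over its standard error. The deposited p-value and its adjusted p-value belong to that statistic. The means were equal in the 4 tables, with a highest difference of 0, and the log2 fold changes added up across the tables to within 1e-09, so they come from a single fit of the 8 libraries. Per the file headers, the adjusted p column is complete, and it differed from a Benjamini-Hochberg adjustment over the listed transcripts by at most 0.00177. No value per library was used here, so the depth of each library is not known. The sum of the means was 5.38e+09. From the deposited standard errors of transcripts with means of 1000 to 100000, 1 independent unit corresponded to a mean of 343, which puts that sum at 1.57e+07 units. The median standard error fell from 0.998 at means up to 1000 to 0.457, 0.135, 0.0559 and 0.0332 in each higher factor of 10, on the log2 scale.

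For the 4 comparisons the adjusted p of the authors' deposited tables was used as it stands, with a threshold of 0.05. The interaction was computed here as the IL-1 log2 fold change with ZNF598 siRNA minus that with control siRNA, divided by the root of the summed squared standard errors, with a two-sided normal p adjusted by Benjamini-Hochberg over transcripts with a mean of at least 10. Those IL-1 comparisons share no library. The size of the IL-1 response was compared between arms over genes whose mean IL-1 log2 fold change was at least 1 with an adjusted p of that mean under 0.05, by 100000 two-sided sign permutations across genes. Agreement of the siRNA effect between the stimulation states was described by shared calls and by Pearson and Spearman correlations over means of at least 50.

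A set of 21 gene lists was tested with limma 3.58.1 (cameraPR on the Wald or interaction statistic, preset correlation 0.01, two-sided, adjusted over the lists of a comparison): NF-κB cytokines and chemokines, NF-κB feedback and signalling, immediate early genes, AU-rich mRNAs bound by ZFP36, mRNA deadenylation and decay factors, GIGYF-4EHP and stalled-ribosome factors, ATF4 and amino acid response, the endoplasmic reticulum unfolded protein response, interferon-stimulated genes, p53 targets, cell cycle genes, replication-dependent histones, cytosolic ribosomal proteins, mitochondrial protein-coding transcripts, cholesterol and fatty acid synthesis, extracellular matrix and osteoblast genes, hypoxia genes, heat shock genes, and leukocyte, endothelial and epithelial markers. Some genes belong to more than 1 list. In particular, many AU-rich mRNAs bound by ZFP36 are also in the NF-κB or immediate early lists, so calls of these lists are not independent. An estimated correlation between the genes of a list could not be run, since it needs values per library; a preset correlation of 0.05 and the rank-based form were run instead. A list call is a statement about the list against all other listed transcripts, not about each member.

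For AU-rich elements, the heptamer UAUUUAU was searched in the longest 3′ UTR annotated for each gene in GENCODE 29 on GRCh38. Transcripts were matched to that annotation by identifier alone: 14806 of the 15789 matched (93.8%), and 14550 (92.2%) had a 3′ UTR. Rising or falling was regressed on the heptamer (logistic regression, statsmodels 0.14.6) with 3′ UTR length, 3′ UTR GC content and mean signal as covariates. The heptamer was also permuted 10000 times within bins of length, GC content and mean. After the siRNA comparisons had been seen, all heptamers carried by at least 100 transcripts were also scanned over 3′ UTRs of at least 100 nt, with 100 shuffles and log2 fold changes limited to 2 in either direction. Coordinates printed are those of GRCh38; the files carry none of their own, and none was converted from hg19.

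Genes were named by a rule: ZNF598; in each comparison the 10 largest rises and 10 largest falls among calls with a mean of at least 50; in the interaction the 10 smallest p-values in each direction; up to 4 members with the smallest p-value in each list; and ZFP36, GIGYF1, GIGYF2, EIF4E2, TNF, CXCL8 and IL6. CXCL8 is listed as IL8, and TNF is not listed. Some genes that the rule takes are not reported here. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. A floor of 20000 on the mean, which is 58.3 independent units and kept 11564 transcripts, was added after seeing the data, since many of the largest changes at the floor of 50 had standard errors above 0.5. The largest changes at that floor are named as well.

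Alternatives were an adjusted p of 0.01, a minimum fold of 2, no filter or other floors on the mean, an empirical null with the statistic rescaled by its robust spread, fold minima of 1.5 and 4 for the response size, and other motifs or the shortest 3′ UTR for AU-rich elements. The interaction step was tested on simulated data of 15789 transcripts: of 50 changed transcripts at each size, 46%, 80%, 98% and 100% were recovered at log2 differences of 0.25, 0.5, 1 and 2, with 16 calls among 15589 unchanged ones. Over 20 further simulations 5.52% of calls were false on average. The simulated noise was normal and drawn with the deposited standard errors, so these runs cannot show whether those errors are right. The list test, on simulated standard normal statistics drawn independently for each gene, called the raised list in 20 of 20 runs and 1 of 360 unchanged lists. It therefore does not cover lists whose genes move together or statistics with a wider spread. In simulated data the motif scan ranked a planted heptamer at 1 (planted effect -0.15, estimate -0.12, 6000 transcripts), and the AU-rich regression returned an odds ratio of 1.25 for a true 1.3 and 1.03 for a true 1, over 14000 genes. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.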

Results

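RNA levels were compared in U2OS cells, a human osteosarcoma line, after transfection of a mismatch control siRNA or an siRNA against ZNF598, each with or without 1 h of IL-1 beta. IL-1 beta is an inflammatory cytokine that activates NF-κB. ZNF598 is a ubiquitin ligase that recognises collided ribosomes, and the series asks what part it plays in regulating genes after transcription. Each of the 4 groups had 2 libraries, and every comparison set 2 libraries against 2 within a fit of all 8. The authors' deposited tables give a log2 fold change with a standard error and an adjusted p-value for 15789 transcripts. Transcripts with an adjusted p below 0.05 were called, and rose and fell are written of such calls. These p-values measure the spread between libraries that the series calls biological duplicates, and nothing in the labels says whether they came from separate transfections or cultures. The depth per library is not known, because no values per library were used here. Precision depended on the mean signal. The median standard error was 0.998 for the 588 transcripts with means up to 1000 and 0.0559 for the 7259 with means between 100000 and 1e+06, on the log2 scale.

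ZNF598 RNA fell with its siRNA in both stimulation states. The listed ZNF598 transcript was ENST00000563630 (GRCh38 chromosome 16, 1997654 to 2009823, minus strand, 12 exons). For it the authors' deposited table gives a log2 fold change of -1.93 ± 0.06 (SE, adjusted p = 3.13e-213) in unstimulated cells. With IL-1 the authors' deposited table gives -1.97 ± 0.06 (SE, adjusted p = 5.21e-222). IL-1 itself moved ZNF598 by -0.01 in control cells (adjusted p = 0.986) and -0.05 in ZNF598 siRNA cells (adjusted p = 0.836) in the authors' deposited tables, neither past the threshold. Among its partners in translational repression, the authors' deposited tables put the scaffold GIGYF1 at -0.14 without IL-1 (adjusted p = 0.0212) and -0.06 with it (adjusted p = 0.409). GIGYF2, a second scaffold, rose by 0.15 in unstimulated cells (adjusted p = 4.31e-04) and stood at 0.01 with IL-1 (adjusted p = 0.924) in the authors' deposited tables. The interaction was not called for GIGYF1 (0.08, adjusted p = 0.878) or GIGYF2 (-0.14, adjusted p = 0.363), so a difference between the stimulation states was not shown. EIF4E2, the cap-binding protein 4EHP, stood at 0.02 and 0.01 (adjusted p = 0.774 and 0.892) in the authors' deposited tables.

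IL-1 given to control siRNA cells asked which genes respond within 1 h, and it raised chemokines and the feedback genes of NF-κB. Among transcripts with means of at least 20000, the authors' deposited table lists the largest log2 rises for the chemokines CXCL3 (6.52 ± 0.08, SE), CXCL8 (5.33 ± 0.13) and CCL20 (4.20 ± 0.20). TNFAIP3, which encodes the NF-κB inhibitor A20, came next at 4.04 ± 0.12 (SE) in the authors' deposited table. The ephrin ligand EFNA1 (3.55), the growth factor CSF2 (3.52), the adaptor TRAF1 (3.40), the ubiquitin ligase BIRC3 (3.23), the chemokine CCL4 (3.10) and the NF-κB inhibitor NFKBIA (2.76) followed in the authors' deposited table, with standard errors of 0.04 to 0.37. The largest falls above that mean were smaller, with the potassium channel subunit KCNAB1 at -0.73 ± 0.15 (SE, adjusted p = 6.22e-05) in the authors' deposited table. The authors' deposited table then gives -0.63 for FAM20A, -0.61 for ZNF746, -0.60 for MST1, -0.59 for ZSCAN12, -0.57 for NKX2-2, -0.55 for SPATA33 and TXNIP, and -0.53 for LRRC2 and MARC2. In all, 656 transcripts were called, 455 higher and 201 lower with IL-1, of which 133 and 26 changed at least 2-fold. With the statistic rescaled by its own spread, an empirical null, 385 were called. At the lower floor of 50 set for naming, the authors' deposited table adds CD69, an activation receptor, at 7.42 ± 0.23 (SE). The 10 largest falls at that floor, -6.25 to -2.44 in the authors' deposited table, all had standard errors above 0.5 and are uncertain.

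By list, 17 of 23 NF-κB cytokines and chemokines rose in control siRNA cells with IL-1 and none fell (18 rose adjusted over the list alone; list adjusted p = 3.50e-149). IL6, an inflammatory cytokine, stood at 1.93 ± 0.16 (SE) in the authors' deposited table. Of 33 NF-κB feedback and signalling genes 25 rose (27 adjusted over the list alone), among them NFKBIZ at 2.18 in the authors' deposited table. The list's adjusted p was too small to be held, and was 2.81e-173 at a preset correlation of 0.05. Of 39 immediate early genes 22 rose and 1 fell (26 and 2 adjusted over the list alone; list adjusted p = 7.89e-79). PPP1R15A stood at 1.29, JUNB at 1.28, ATF3 at 1.13 and IER2 at 1.08 in the authors' deposited table. AU-rich mRNAs bound by ZFP36, a protein that sends such mRNAs to decay, rose in 24 of 31 cases (25 adjusted over the list alone; list adjusted p = 4.90e-267). ZFP36 itself rose by 1.82 ± 0.06 (SE, adjusted p = 9.56e-182) in the authors' deposited table. Of 79 cytosolic ribosomal protein genes 6 rose by small amounts, such as RPS20 at 0.19 in the authors' deposited table (14 rose adjusted over the list alone; list adjusted p = 3.76e-05).

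Smaller numbers moved in 4 further lists called in control siRNA cells. Among p53 targets 4 of 24 rose (4 adjusted over the list alone; list adjusted p = 6.02e-04, but 0.123 by the rank-based form), including BTG2 and PLK2. Of 36 ATF4 and amino acid response genes 3 rose (3 adjusted over the list alone; list adjusted p = 6.02e-04, rank-based adjusted p = 0.270). Of 36 mRNA deadenylation and decay factors 5 rose and 1 fell (5 and 2 adjusted over the list alone; list adjusted p = 7.29e-04, rank-based adjusted p = 0.479). Of 25 extracellular matrix and osteoblast genes 5 rose (6 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0145, but adjusted p = 0.0929 at a preset correlation of 0.05). Their median log2 fold change was 0.05 and their mean -0.01. The remaining 12 lists were not called. Members that rose and fell numbered 0 and 1 of 20 GIGYF-4EHP and stalled-ribosome factors, 2 and 1 of 35 interferon-stimulated genes, and 2 and 0 of 26 cholesterol and fatty acid synthesis genes. They numbered 0 and 2 of 17 hypoxia genes and 1 and 0 of 14 heat shock genes. No member was past the threshold among 18 genes of the endoplasmic reticulum unfolded protein response, 34 cell cycle genes, 45 histone genes, 5 mitochondrial transcripts, 7 endothelial markers and 8 epithelial markers. Of 6 leukocyte markers 1, ITGAM, rose.

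IL-1 given to ZNF598 siRNA cells asked the same question with less ZNF598, and raised many of the chemokines and feedback genes by smaller folds. Above a mean of 20000 the authors' deposited table lists log2 rises of 5.40 for CXCL3, 3.87 ± 0.13 (SE, adjusted p = 6.62e-189) for CXCL8, 3.29 for CCL20 and 3.10 for TNFAIP3. The authors' deposited table gives 2.73 for CCL4, 2.5 for EFNA1, 2.27 for TRAF1, 2.22 for CSF2, 2.21 for C8orf4 and 2.17 for NFKBIA. Among the largest falls, the exchange factor MCF2 stood at -1.03 ± 0.21 (SE, adjusted p = 1.02e-04) in the authors' deposited table. The authors' deposited table puts the kinetochore motor CENPE at -0.68 ± 0.10 (SE, adjusted p = 6.11e-10), the centrosomal protein CEP290 at -0.62 and the scaffold AKAP9 at -0.59 ± 0.06 (SE, adjusted p = 2.05e-18). ZNF154 (-0.69), the chemokine CCL24 (-0.68), YPEL4 (-0.61), FAM20A (-0.59), ANKRD12 (-0.58) and KCNAB1 (-0.57) complete these falls in the authors' deposited table. MCF2, CENPE and AKAP9 stand in the highest decile of A content of the 10977 transcripts with a matched sequence and a mean of at least 20000. A total of 624 transcripts were called, 394 higher and 230 lower, with 90 and 20 of them changed at least 2-fold. The empirical null left 295. With the control siRNA comparison it shared 251 higher calls, where independent lists would share 11.4, and 38 lower calls, where they would share 2.93. Another 2 transcripts moved in opposite directions. At the floor of 50 the 10 largest falls, -6.64 to -2.07 in the authors' deposited table, were all below a mean of 20000, and 9 had standard errors above 0.5.

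In the lists, 15 of 23 NF-κB cytokines and chemokines rose in ZNF598 siRNA cells with IL-1 (18 adjusted over the list alone; list adjusted p = 8.03e-102), with IL6 at 1.89 in the authors' deposited table. Of 33 NF-κB feedback and signalling genes 26 rose (28 adjusted over the list alone; list adjusted p = 7.06e-241), and NFKBIZ stood at 1.98 in the authors' deposited table. Of 39 immediate early genes 28 rose (30 adjusted over the list alone; list adjusted p = 7.52e-99). PPP1R15A stood at 1.29, ATF3 at 1.04, IER2 at 0.92 and JUN at 0.81 in the authors' deposited table. AU-rich mRNAs bound by ZFP36 rose in 22 of 31 cases (26 adjusted over the list alone; list adjusted p = 1.22e-219). Among p53 targets 6 of 24 rose (10 adjusted over the list alone; list adjusted p = 4.17e-09), PLK3 by 0.37 and PLK2 by 0.26 in the authors' deposited table. Of 36 ATF4 and amino acid response genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 4.40e-11). Of 25 extracellular matrix and osteoblast genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 4.10e-04). CYR61 stood at 0.41 and CTGF at 0.27 in the authors' deposited table. Decay factors were also called (3 of 36 rose and 1 fell, also adjusted over the list alone; list adjusted p = 0.00151, rank-based adjusted p = 0.467). The other 13 lists were not called, with 0 of 79 ribosomal protein genes and 0 of 17 hypoxia genes past the threshold.

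The difference between these IL-1 effects, computed here as the interaction, asked whether the siRNA changed the response. It was called for 66 transcripts, 13 higher and 53 lower in ZNF598 siRNA cells, of which 5 and 49 had means of at least 20000. Of the 53 lower ones, 18 were among the genes with a mean IL-1 log2 fold change of at least 1. The log2 IL-1 effect of BIRC3 (GRCh38 chromosome 11, 102317495 to 102337734) differed by -1.60 ± 0.08 (SE, adjusted p = 1.39e-82), and that of the activation receptor CD69 by -3.30 ± 0.32 (SE, adjusted p = 3.98e-21). For CXCL8 it differed by -1.46 ± 0.18 (SE, adjusted p = 4.32e-12). The interferon-pathway transcription factor IRF1 (-0.88), TRAF1 (-1.13), CXCL3 (-1.11), NFKBIA (-0.59), CCL2 (-0.88), ANKRD12 (-0.74) and AKAP9 (-0.74) were also among those with the 10 smallest p-values in that direction. ZFP36 (GRCh38 chromosome 19, 39406813 to 39409412) also responded less, by -0.57 ± 0.09 (SE, adjusted p = 1.66e-07). IL6 differed by -0.04 (adjusted p = 0.994) and ZNF598 by -0.04 (adjusted p = 0.970). Higher IL-1 effects were called for PTCHD2 (3.00), NKX2-5 (0.40), MME (5.57), TNN (3.95), NLRP12 (4.83), NKX2-2 (0.56), ITM2A (3.94), ZSCAN25 (0.44) and TRIM49 (9.01 ± 2.27, SE), several of them with means far below 20000.

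Over the 133 genes whose mean IL-1 log2 fold change was at least 1, chosen without favouring either arm, the median response was 1.79 in control cells and 1.35 in ZNF598 siRNA cells. The median difference was -0.48, with 106 genes below 0 and 27 above (permutation p = 1e-05, the smallest that 100000 sign permutations can give; across genes, which are not independent replicates). NF-κB cytokines and chemokines differed by a median of -0.36 (18 of 23 below 0, permutation p = 6.10e-04) and NF-κB feedback genes by -0.16 (24 of 33 below 0, permutation p = 0.0013). Immediate early genes differed by -0.01 (21 of 39 below 0, permutation p = 0.774). In the list test of the interaction, 7 of 23 cytokines were lower and none higher (9 lower adjusted over the list alone, list adjusted p = 1.13e-21, rank-based adjusted p = 0.00113). Of 33 feedback genes 11 were lower (13 lower and 1 higher adjusted over the list alone, list adjusted p = 1.24e-36, rank-based adjusted p = 0.00232). Of 31 AU-rich mRNAs bound by ZFP36, 9 were lower (12 lower and 2 higher adjusted over the list alone, list adjusted p = 7.32e-21, rank-based adjusted p = 0.00415). Those 9 were CXCL8, CXCL3, CSF2, CCL2, TNFAIP3, IRF1, JUNB, MYC and ZFP36. All but ZFP36 also belong to the NF-κB or immediate early lists, so this call is not separate evidence. No single member passed among 79 ribosomal protein genes (median -0.05, list adjusted p = 3.55e-04, but adjusted p = 0.0681 at a preset correlation of 0.05). The same held for 5 mitochondrial transcripts (median -0.26, list adjusted p = 0.00266) and 36 ATF4 genes (median 0.04, list adjusted p = 0.00927, but adjusted p = 0.123 at a preset correlation of 0.05). The 5 mitochondrial transcripts, of 13 in the list, moved alike, from -0.33 to -0.17. Preset correlations of 0.01 and 0.05 may be too low for them, and their own correlation could not be estimated. Across deciles of A content of 10977 transcripts the median difference itself ran from 0.03 to -0.04. The other 15 lists were not called.

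**Figure D1:**
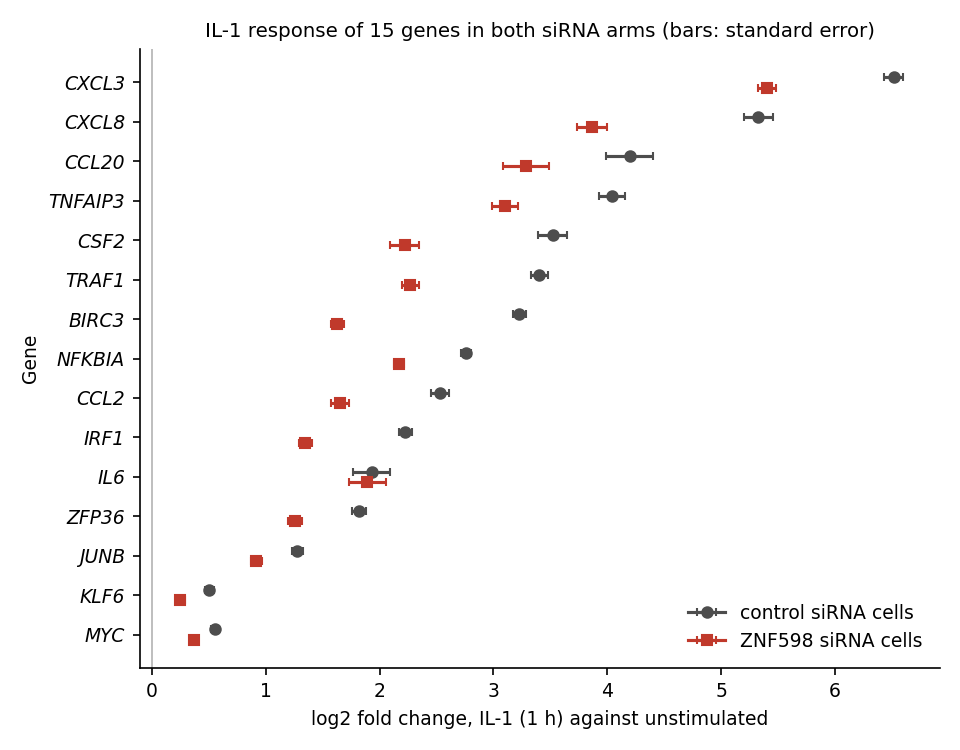
Log2 fold change with IL-1 (points, bars are standard errors) for 15 named genes in control siRNA and ZNF598 siRNA cells, from the authors' deposited tables. CXCL3 goes from 6.52 to 5.40 and BIRC3 from 3.23 to 1.63, whereas IL6 stays at 1.93 and 1.89.

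The siRNA comparison in unstimulated cells asked what the ZNF598 siRNA changes on its own, and it reached about as many transcripts as it left. Of the 15789 transcripts 7660 were called (48.5%), 3854 higher and 3806 lower, with 578 and 174 of them changed at least 2-fold. An empirical null, which takes the typical transcript as unchanged, left 1019. Of the 7660 calls, 3215 higher and 3605 lower ones had means of at least 20000, with 182 and 75 of them changed at least 2-fold. The largest log2 rises above a mean of 20000 in the authors' deposited table were those of CA9, a carbonic anhydrase induced by low oxygen (3.73 ± 0.16, SE, adjusted p = 2.83e-113), and F13A1, a subunit of coagulation factor XIII (3.72 ± 0.13, adjusted p = 3.08e-181). The complement protein C3 stood at 3.25 ± 0.15 (SE, adjusted p = 7.80e-103) in the authors' deposited table. The growth factor PDGFB (2.37), the proteoglycan LUM (2.36), NYAP2 (2.36), the muscle proteins CSRP3 (2.29) and XIRP1 (2.27), TMEM45A (2.22) and ENST00000511828, which has no symbol (2.43), complete the 10 in the authors' deposited table. The largest falls in the authors' deposited table were those of the receptor CD180 (-2.39), the neuropeptide precursor VGF (-2.11), the Polycomb-related SFMBT2 (-2.03), the neurotrophin receptor NTRK3 (-2.00) and ZNF598 (-1.93). Next in the authors' deposited table were WSCD1 (-1.78), the synaptic vesicle protein SYP (-1.77), the methionine salvage enzyme APIP (-1.71), the vesicle coat protein SEC23A (-1.67) and the fatty acid oxidation enzyme HADH (-1.66). Of these 10 falls 6 carried a 3′ UTR site from the heptamer scan reported below, against 3 of the 10 rises. At the floor of 50 the 10 largest rises, 4.14 to 6.29, and falls, -4.90 to -2.63 in the authors' deposited table, all had means below 20000, and 9 and 10 of them had standard errors above 0.5.

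NF-κB targets were already higher in unstimulated ZNF598 siRNA cells. CXCL8 (GRCh38 chromosome 4, 73740506 to 73743716) rose by 1.58 ± 0.13 (SE, adjusted p = 4.37e-32) in the authors' deposited table. CD69 rose by 2.91, CSF2 by 1.88, TRAF1 by 1.52, IL6 by 1.33, CCL20 by 1.23, BIRC3 by 1.11 and CXCL3 by 0.99 in the authors' deposited table, while ZFP36 fell by 0.36 (adjusted p = 4.51e-08). Of 23 cytokines and chemokines 16 rose (16 rose and 1 fell adjusted over the list alone; list adjusted p = 2.15e-06), with IL32 at 1.63 and CSF1 at 0.79 in the authors' deposited table. Of 33 feedback genes 23 rose and 1 fell (26 and 1 adjusted over the list alone; list adjusted p = 1.46e-11), with TNFAIP2 at 1.12 and TNIP1 at 0.69 in the authors' deposited table. AU-rich mRNAs bound by ZFP36 rose in 20 and fell in 5 of 31 cases (20 and 7 adjusted over the list alone; list adjusted p = 2.15e-06), with VEGFA at 0.77 in the authors' deposited table.

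Stress, growth and synthesis genes moved too in unstimulated cells. Hypoxia genes rose in 14 and fell in 1 of 17 cases (15 and 1 adjusted over the list alone; list adjusted p = 3.02e-14). BNIP3, a mitophagy receptor, stood at 1.15 and the glycolytic enzyme HK2 at 0.86 in the authors' deposited table. Of 36 ATF4 and amino acid response genes 24 rose and 4 fell (24 and 4 adjusted over the list alone; list adjusted p = 1.45e-08). DDIT4 stood at 0.97, VLDLR at 0.73, SESN2 at 0.66 and asparagine synthetase, ASNS, at 0.64 in the authors' deposited table. Interferon-stimulated genes rose in 22 and fell in 1 of 35 cases (24 and 1 adjusted over the list alone; list adjusted p = 6.44e-06). GBP1 stood at 1.53 and SAMD9L at 1.46 in the authors' deposited table. Cytosolic ribosomal protein genes fell in 53 and rose in 1 of 79 cases (54 and 1 adjusted over the list alone; list adjusted p = 2.15e-06), with RPS2 at -0.53 in the authors' deposited table. Of 45 replication-dependent histone genes 27 fell and none rose (28 fell adjusted over the list alone; list adjusted p = 6.44e-06). Of 34 cell cycle genes 18 fell and 4 rose (18 and 4 adjusted over the list alone; list adjusted p = 1.65e-04). The linker histone HIST1H1A stood at -0.87 and the mitotic regulators CDC20 and FOXM1 at -0.54 and -0.51 in the authors' deposited table. Genes of cholesterol and fatty acid synthesis fell in 15 and rose in 4 of 26 cases (15 and 5 adjusted over the list alone; list adjusted p = 0.00779, but adjusted p = 0.0633 at a preset correlation of 0.05). Of 18 genes of the endoplasmic reticulum unfolded protein response 10 fell and 3 rose (10 and 3 adjusted over the list alone; list adjusted p = 0.0141, but adjusted p = 0.0633 at a preset correlation of 0.05). The chaperone HYOU1 stood at -1.09 in the authors' deposited table.

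The other 10 lists were not called in unstimulated cells, although many members were. Members that rose and fell numbered 8 and 5 of 39 immediate early genes (adjusted p = 0.575), 8 and 17 of 36 decay factors (adjusted p = 0.153). They numbered 3 and 6 of 20 GIGYF-4EHP and stalled-ribosome factors (adjusted p = 0.0552) and 8 and 11 of 24 p53 targets (adjusted p = 0.647). Among further lists they numbered 10 and 8 of 25 matrix genes (adjusted p = 0.888), 2 and 8 of 14 heat shock genes (adjusted p = 0.0534), and 0 and 2 of 5 mitochondrial transcripts (adjusted p = 0.522). Among decay factors the authors' deposited table puts ZFP36L2, a relative of ZFP36, at -0.97 and KHSRP at -0.49. Of the marker lists 4 of 8 epithelial genes rose and 2 fell (adjusted p = 0.464), with KRT7 at 1.75 and CLDN4 at 1.04 in the authors' deposited table. Of 7 endothelial genes 2 rose and 1 fell (adjusted p = 0.756), and 1 of 6 leukocyte genes fell (adjusted p = 0.962).

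With IL-1 the siRNA comparison asked the same in stimulated cells, and CA9, F13A1, C3, LUM, PDGFB and XIRP1 were again among the largest rises. The authors' deposited table gives log2 fold changes of 4.05 ± 0.16 (SE, adjusted p = 8.17e-133) for CA9, 3.07 for F13A1, 3.02 for the smooth muscle actin ACTG2 and 2.71 for C3. The authors' deposited table gives 2.63 for ALPK3, 2.57 for XIRP1, 2.49 for LUM and the alkaline phosphatase ALPP, 2.38 for PDGFB and 2.35 for EPPK1, above a mean of 20000. The largest falls in the authors' deposited table were those of CD180 (-2.34), NTRK3 (-2.02), VGF (-2.02), ZNF598 (-1.97), SFMBT2 (-1.93), MCF2 (-1.86), APIP (-1.84), SEC23A (-1.72), SYP (-1.72) and CCL24 (-1.69). In all 7904 transcripts were called (50.1%), 3918 higher and 3986 lower, with 581 and 214 of them changed at least 2-fold. The empirical null left 983. Of the 7904 calls, 3260 higher and 3735 lower ones had means of at least 20000, with 173 and 96 of them changed at least 2-fold. Both siRNA comparisons, which share no library, called 3106 transcripts higher, where independent lists would share 956, and 3160 lower, where they would share 961. Another 9 were called in opposite directions. Across transcripts with means of at least 50 the log2 fold changes correlated with a Pearson r of 0.603 and a Spearman rho of 0.739. Above a mean of 20000 these correlations were 0.936 and 0.914, across transcripts, which are not independent replicates. Variation shared by the libraries of an siRNA arm, such as a transfection split into both states, would also give shared calls and correlation. At the floor of 50 the extremes, 3.42 to 4.82 and -5.64 to -2.53 in the authors' deposited table, had standard errors above 0.5 in 8 and 9 of 10 cases.

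**Figure D2:**
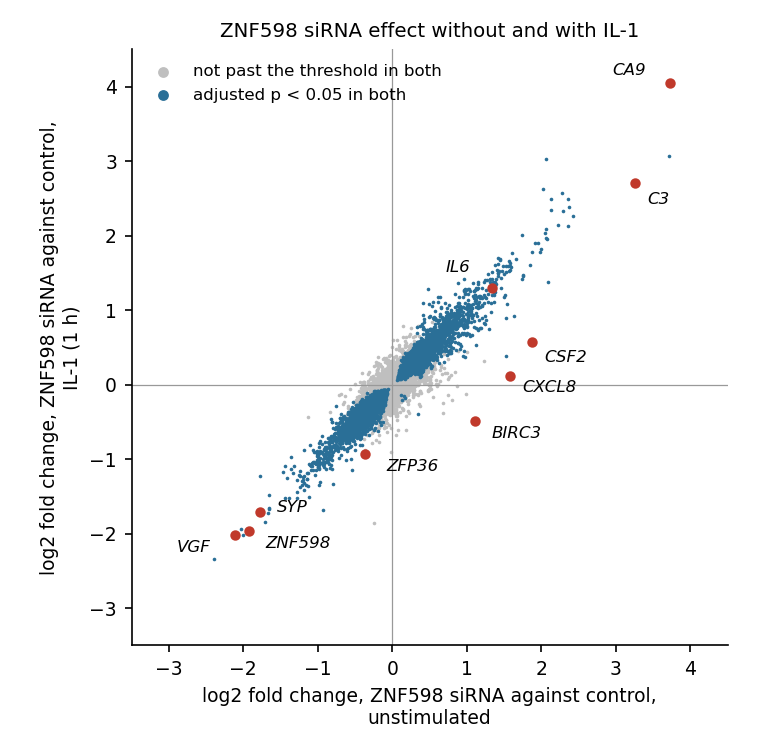
Log2 fold change with ZNF598 siRNA in unstimulated cells (x) and in IL-1 cells (y) for the 11564 transcripts with means of at least 20000, from the authors' deposited tables; blue points were called in both. The Pearson correlation across these transcripts is 0.936, and ZNF598 sits at -1.93 and -1.97.

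The NF-κB targets stood differently in IL-1 cells, where fewer were higher with ZNF598 siRNA. In the authors' deposited table CXCL8 was at 0.12 (adjusted p = 0.482), CD69 at -0.39 (adjusted p = 0.133), and CXCL3 at -0.13 (adjusted p = 0.196). The authors' deposited table puts NFKBIA at -0.06 (adjusted p = 0.234) and IRF1 at -0.02 (adjusted p = 0.850). BIRC3 (-0.49, adjusted p = 1.53e-16) and ZFP36 (-0.93, adjusted p = 5.19e-48) fell in the authors' deposited table. IL6 (1.29, adjusted p = 2.13e-14), CSF2 (0.58) and TRAF1 (0.39) rose in the authors' deposited table. Of 23 cytokines and chemokines 8 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.117). Of 33 feedback genes 18 rose and 3 fell (18 and 4 adjusted over the list alone; list adjusted p = 0.0175, but adjusted p = 0.115 at a preset correlation of 0.05). The difference from unstimulated cells is the interaction, with list adjusted p of 1.13e-21 and 1.24e-36 for these lists. By the rank-based form these were 0.00113 and 0.00232. AU-rich mRNAs bound by ZFP36 rose in 12 and fell in 7 of 31 cases (12 and 8 adjusted over the list alone; list adjusted p = 0.112).

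Genes outside the NF-κB lists were also called in IL-1 cells. Hypoxia genes rose in 16 of 17 cases (list adjusted p = 1.19e-14), ATF4 and amino acid response genes in 26 of 36 with 2 that fell (list adjusted p = 1.33e-10). Interferon-stimulated genes rose in 22 of 35 cases and fell in 1 (23 and 1 adjusted over the list alone; list adjusted p = 2.30e-05). Ribosomal protein genes fell in 62 and rose in 1 of 79 cases (list adjusted p = 4.74e-09). Histone genes fell in 29 of 45 (31 adjusted over the list alone; list adjusted p = 5.20e-07), and cell cycle genes fell in 19 and rose in 3 of 34 (list adjusted p = 1.41e-04). Adjusted over the list alone, the counts for hypoxia, ATF4, ribosomal protein and cell cycle genes were equal to these. The authors' deposited table puts HK2 at 0.97, BNIP3 at 1.08, SESN2 at 0.73, PSAT1 at 0.59, GBP1 at 1.59, OAS3 at 1.04, RPS2 at -0.51, HIST1H1A at -1.04 and CDC20 at -0.53. Unfolded protein response genes fell in 9 and rose in 4 of 18 cases (list adjusted p = 0.0282) and heat shock genes fell in 8 and rose in 1 of 14 (list adjusted p = 0.0388), but both had an adjusted p = 0.115 at a preset correlation of 0.05. The remaining 12 lists were not called. Members that rose and fell in IL-1 cells numbered 10 and 9 of 39 immediate early genes, 7 and 14 of 36 decay factors and 3 and 5 of 20 GIGYF-4EHP factors. The numbers were 12 and 9 of 24 p53 targets, 4 and 12 of 26 cholesterol and fatty acid synthesis genes and 11 and 8 of 25 matrix genes. All 5 mitochondrial transcripts fell (list adjusted p = 0.0975), with MT-ATP6 at -0.60 in the authors' deposited table. Their interaction list adjusted p was 0.00266, at a preset correlation that may be too low for them. Of the marker lists 5 of 8 epithelial genes rose and 2 fell, 2 of 7 endothelial genes rose and 2 of 6 leukocyte genes rose.

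**Figure D3:**
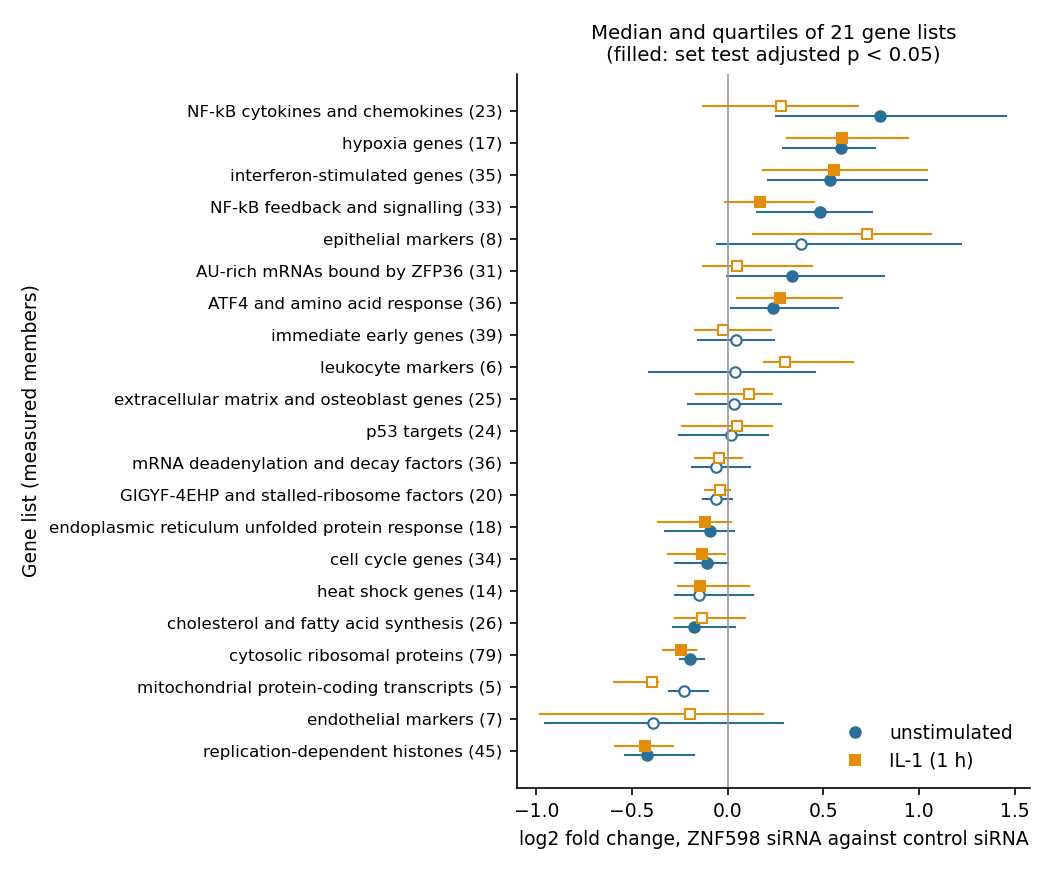
Median log2 fold change with ZNF598 siRNA of the members of each gene list, in unstimulated and in IL-1 cells, with the quartiles of the members as bars and filled symbols for lists called in the list test. NF-κB cytokines go from a median of 0.80 without IL-1 to 0.28 with it.

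AU-rich elements were examined because ZFP36 and related proteins act through them. Among 14550 genes with an annotated 3′ UTR, the heptamer UAUUUAU stood in 38.6% of those that rose with ZNF598 siRNA in unstimulated cells and in 32.7% of the others. The difference held at a given length, GC content and mean (odds ratio 1.13, 95% interval 1.03 to 1.24 after adjustment for these, two-sided permutation p = 0.0053). Genes that fell there carried it in 35.5% of cases against 33.8% of the others, but less often at a given length, GC content and mean (odds ratio 0.831, 0.754 to 0.916; permutation p = 3.00e-04). In IL-1 cells the odds ratio was 1.07 for genes that rose (0.980 to 1.18; permutation p = 0.0980). It was 0.854 for genes that fell (0.776 to 0.940; permutation p = 6.00e-04), although 36.5% of them and 33.4% of the others carried the heptamer. By permutation, the result for rising genes in unstimulated cells was not past the threshold with the nonamer, the pentamer or the shortest 3′ UTR. That for falling genes was not past it with the nonamer or the pentamer there, or with the pentamer in IL-1 cells, and that for rising genes in IL-1 cells passed it above a mean of 20000. For IL-1 itself, genes that rose in control cells had an odds ratio of 1.65 (1.31 to 2.07; permutation p = 0.0001, the smallest that 10000 permutations can give). In ZNF598 siRNA cells it was 1.53 (1.20 to 1.96; permutation p = 6.00e-04). Genes that fell with IL-1 had odds ratios of 1.51 (1.07 to 2.13; permutation p = 0.0224) and 1.21 (0.875 to 1.66; permutation p = 0.210) in the same arms.

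A scan of all heptamers in 3′ UTRs, chosen after the siRNA comparisons had been seen, put a pair of overlapping motifs first among 10725 transcripts. Carriers of ACAATGA (1327 transcripts, estimate -0.10 log2 over the mean of both siRNA comparisons, t statistic -9.83) and of CAATGAA (1483, -0.10, t statistic -9.80) were lower. Next came carriers of GCTCGTC (177, -0.19, t statistic -6.80). The next heptamer had a t statistic of -4.62, the highest positive one 4.46, and the largest absolute value in 100 shuffles was 4.93. Among the 579 carriers of both overlapping motifs as the joined 8-base site, the median log2 fold change was -0.13 and 47.2% fell in unstimulated cells, against -0.01 and 28.5% of the 8506 transcripts with none of the motifs. The ZNF598 transcript itself holds ACAATGA at positions 671 to 677, counted from 1 at its start, and the reverse complement of GCTCGTC at 655 to 661. It holds no copy of CAATGAA, and so not the joined 8-base site. Both lie within 25 nt of exon 4, in the coding sequence (GRCh38 chromosome 16, 2002598 to 2002622, minus strand). Such a pair within 30 nt occurs in 4 of the 14806 matched transcripts.

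**Figure D4:**
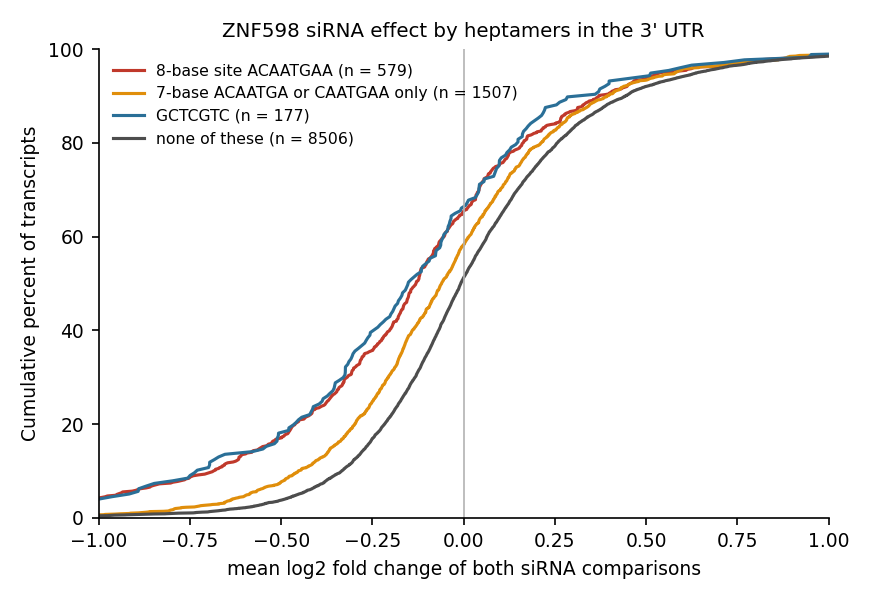
Distribution of the log2 fold change with ZNF598 siRNA (mean of both stimulation states) for transcripts grouped by the heptamers in their 3′ UTR. The curve of the 579 transcripts with the 8-base site lies to the left, with a median of -0.13 against -0.01 for the 8506 with none.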

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

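The interaction and its list tests were planned, and all tests of explanations in this part were chosen after the results were seen. The IL-1 effect differed between control and ZNF598 siRNA cells for 66 transcripts and, over the 133 genes raised by IL-1, by a median of -0.48 on the log2 scale. Median differences of lists called in the interaction were -0.36 for NF-κB cytokines and chemokines, -0.16 for NF-κB feedback and signalling, -0.19 for AU-rich mRNAs bound by ZFP36, 0.037 for ATF4 and amino acid response genes, -0.052 for cytosolic ribosomal proteins and -0.26 for mitochondrial transcripts. The ATF4 and ribosomal protein lists were no longer called at a preset correlation of 0.05 (list adjusted p = 0.123 and 0.0681). Members of the AU-rich list overlap with the NF-κB lists, and the mitochondrial transcripts moved alike. Across deciles of A content the median difference of all transcripts ran from 0.03 to -0.04, a span of the size of the ATF4 and ribosomal protein differences, and these lists were not tested against it.

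Among single genes, the interaction was called for inflammatory and immediate early genes: BIRC3 (-1.60), IRF1 (-0.88), TRAF1 (-1.13), CD69 (-3.30), CXCL3 (-1.11), NFKBIA (-0.59), CCL2 (-0.88), CXCL8 (-1.46), CSF2 (-1.30), TNFAIP2 (-0.59), IL32 (-0.71), ZFP36 (-0.57), TNFAIP3 (-0.94), EFNA1 (-1.06), JUNB (-0.36), KLF6 (-0.25), CSF1 (-0.36) and MYC (-0.18). It was called for ANKRD12 (-0.74), AKAP9 (-0.74), CENPE (-0.89), CEP290 (-0.68) and MCF2 (-1.61). Higher IL-1 effects with ZNF598 siRNA were called for PTCHD2 (3.00), NKX2-5 (0.40), MME (5.57), TNN (3.95), NLRP12 (4.83), NKX2-2 (0.56), ITM2A (3.94), ZSCAN25 (0.44) and TRIM49 (9.01). Several of these higher ones have low means and large standard errors.

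The smaller IL-1 folds in ZNF598 siRNA cells go with higher starting levels: the median siRNA effect on the 133 genes was 0.68 without IL-1 and 0.11 with it. Because the 4 log2 fold changes add up, the gap between these siRNA effects restates the IL-1 difference and is not a second observation. Variation in the unstimulated ZNF598 siRNA libraries would move the starting level and the IL-1 fold together. A shift in normalization could not be judged from the median difference of 0.000581 over all transcripts. Normalization itself centres the typical transcript, and the median log2 fold change was 0.0021 to 0.0044 in the 4 comparisons. RNA of IL-1-treated cells mixed into the unstimulated ZNF598 siRNA libraries stays open for the genes as a set. At the best single share of 8.3%, 9.62% of 52 genes lay outside 2 standard errors, widened by the spread of the comparison's statistic. A mixture has the same share for all genes, whereas CXCL3 alone would need 1.18%, NFKBIZ 1.08% and BIRC3 20.4%. No single share gives the values of these 3 genes. A similar linear increment on a higher starting level may account for part of the pattern, with a median ratio of increments of 0.942 (quartiles 0.732 and 1.32). Of the 133 genes 2, BIRC3 and ZFP36, lay over 3 widened standard errors below what a similar increment predicts and 0 above. The ratio cannot tell a similar increment from similar levels after IL-1, where the median siRNA effect was 0.11. Whether the higher starting level comes from the loss of ZNF598 or from another effect of this siRNA was not tested.

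Of the 10977 transcripts with a matched sequence and a mean of at least 20000, which leaves out ANKRD12, 17 were called lower in the interaction with a mean IL-1 log2 fold change between -0.25 and 0.25, and many are long and A-rich, such as CENPE, AKAP9, GOLGA4, EEA1 and ASPM. Greater power for long or abundant transcripts is argued against by 11 of the 17 lying in the highest decile of A content, where 2.12 were expected at matched mean and length and 8 was the highest of 10000 permutations. A trend with base composition over the transcriptome, as library preparation could give, may be part of the shift: transcripts similar to those 11, outside the 17, had a median difference of -0.14. It does not reach the members outside that decile, whose own differences were -0.40 to -0.21. Transcripts similar to each of them had median differences of -0.0077 to 0.0242. Whether the trend accounts for all of the shift in those 11 stays open. Of them 7, and of the 17 members 13, lay more than 3 standard errors below similar transcripts, but all were chosen for a low difference. Of all 1062 transcripts in that decile with as small a mean response, called or not, 8 lay more than 3 standard errors below similar transcripts and 2 above (exact two-sided binomial p = 0.109). A single aberrant library could not be examined, and no biological explanation was tested.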

How the results depend on the processing

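Most alternatives were chosen beforehand, and the floor of 20000 on the mean and the restriction to transcripts without seed hexamers were chosen after the results were seen. No paired analysis was possible because the tables hold comparison results and no values per library; for the same reason leaving out each replicate, a replicate block, edgeR or DESeq2 on counts, a fit of 4 libraries and an estimated correlation in the list test were not run. With no value per library, depth limits are known only through the standard errors, whose median was 0.998 at means up to 1000.

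Counts of called transcripts moved with the threshold, the minimum fold and the null distribution. With an adjusted p of 0.01 it was 436 in control and 383 in ZNF598 siRNA cells. A minimum of 2-fold left 159 and 110, and 752 and 795 in the siRNA comparisons (unstimulated, IL-1), by construction. An empirical null left 385 (80.0% higher, against 69.4% in the deposited tables) and 295 (81.0% against 63.1%) for IL-1 and 1019 and 983 for the siRNA, because it widens the null by the robust spread of the statistic, 1.19, 1.25, 3.20 and 3.33 in these comparisons. Under the other alternatives run, the IL-1 counts were 549 to 656 and 568 to 627, the siRNA counts were 6293 to 7666 and 6517 to 7908, the interaction count was 45 to 66, and the difference in IL-1 response size was -0.92 to -0.30. The ZNF598 transcript stayed past the threshold in both siRNA comparisons under each alternative run. Of the single-gene results tested, 130 stayed past the threshold at an adjusted p of 0.01 and 118 under the empirical null, with 11 and 23 lost.

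The correlation of the siRNA effects was 0.936 above a mean of 20000, against 0.603 above 50; the floor removes the transcripts with the largest standard errors. Of 105 list tests 43 were called, 35 at a preset correlation of 0.05 (35 shared), 41 by the rank-based form (36 shared) and 44 above a mean of 20000 (42 shared).

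AU-rich results also moved, judged by the logistic p. For genes that rose in unstimulated cells the odds ratio was 1.04 with the nonamer, 1.11 with the pentamer and 1.03 with the shortest 3′ UTR, none past the threshold, and for genes that fell it was 0.940 with the nonamer. For genes that rose in IL-1 cells it turned to 0.985 with the shortest 3′ UTR, not past the threshold in either case, and was 1.13, past it, above a mean of 20000. For genes that fell there it was 0.884 with the shortest 3′ UTR, no longer past the threshold, although the permutation p was 0.0245. By permutation, the falls were also not past it with the pentamer in either state (permutation p = 0.246 and 0.155). The cause was not tested.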

Other observations

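The siRNA comparisons and the list test were planned, while the scans of 3′ UTRs and the tests of explanations were chosen after the results were seen. Regulators of mRNA decay moved with the siRNA while their list as a whole was not called. In the authors' deposited tables the decay factor ZFP36L2 stood at -0.97 without and -0.92 with IL-1, and KHSRP, a protein that binds AU-rich elements, at -0.49 and -0.55. The transcription factor KLF2, an immediate early gene, rose by 2.07 and 1.95, and CTGF, a target of YAP and TGF-beta signalling, fell by 0.63 and 0.46 in the authors' deposited tables. TNIP1, which restrains NF-κB signalling, rose by 0.69 in both states and the vascular growth factor VEGFA by 0.77 in both in the authors' deposited tables.

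In 3′ UTRs the heptamers with the highest t statistic for the IL-1 effect were AU-rich: TATTTAA in control cells (4.78) and TATTTAT in ZNF598 siRNA cells (5.06). Neither passed the largest absolute value of the shuffles, 5.30 and 5.63.

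About as many transcripts were called as not in each siRNA comparison. Standard errors that are too small for these comparisons stay open: the interaction statistic had a robust spread of 1.07, but variation shared by the libraries of one siRNA arm, such as a transfection split into both states, cancels in it, and the siRNA statistics spread by 3.20 and 3.33. Pairing of the siRNA's seed with 3′ UTRs may lower the transcripts that carry the site, although the siRNA's sequence is not given in the sources used here. Of the 10 largest falls at the higher floor on the mean, 6 in unstimulated cells and 4 in IL-1 cells carried such a site. Of the largest rises, 3 of 10 in unstimulated cells and 2 of the 9 with a searched 3′ UTR in IL-1 cells did. Any of the motifs stood in 2219 of the 10725 scanned transcripts. Whether pairing lowered the named genes was not tested. The leading heptamer had a t statistic of -9.83, against at most 4.93 in shuffles. It and the reverse complement of GCTCGTC lie within 25 nt of the ZNF598 coding sequence, where an siRNA could pair. CAATGAA does not occur there, but it shares the 6 bases CAATGA with the leading heptamer. If the standard errors hold, direct pairing could not be the whole cause of the calls. Of the 3307 transcripts with neither seed hexamer 55.0% were past the threshold in unstimulated cells, against 59.2% of all 10725 scanned. How much follows from the loss of ZNF598 itself stays open, because a single ZNF598 siRNA condition was compared and no rescue or other ZNF598 siRNA was used here.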
